A study of Mus musculus with 14 samples.

How the data were processed

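RNA of sorted mouse mammary cells was measured on 14 Agilent 2-colour expression arrays, each with 43379 non-control spots for 41174 probes. Per the labels' protocols, glands were dissociated mechanically and enzymatically, cells were sorted by flow cytometry, and total RNA was labelled with Cy5 by the Quick Amp kit. The Cy3 channel of every array held a commercial reference RNA, a mix of 11 mouse cell lines, so each value is a log ratio of the sorted cells over that mix. Per the submitters' processing notes and the file headers, the scans were quantified with Agilent Feature Extraction 9.5.3.1. The scanner files, as deposited, give for each spot the mean intensity and the local background intensity of both channels on a linear scale. Per the file headers they also give the scanner software's own log ratio, log10 of Cy5 over Cy3, after its background subtraction and dye normalization. Further columns as deposited hold flags for spots that were outliers, saturated or well above background, which have no unit.

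The series table deposited by the authors holds log2 ratios. Set against the scanner files, each of its columns was the scanner's log10 ratio turned to log2, with correlations from 0.990 to 1.000 over probes. Its column medians ran from -0.0182 to 0.102, so the columns had not been centred, and its direction was Cy5 over Cy3 on every array. It was used only as an alternative.

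The values reported here were computed from the mean and local background intensities in R 4.3.3 with limma 3.58.1. Local backgrounds marked as outliers, 7 to 381 per array and channel, were replaced by the median of that array and channel. This step was chosen after seeing the data, because on 3 arrays a few extreme local backgrounds spoiled the fit of the background model. The fitted SD of the background ran from 0.549 to 776 with the backgrounds as given and from 0.551 to 2.28 after the replacement. Background was corrected with normexp (offset 50), fitted on all spots, and ratios were normalized within each array by loess with control spots at weight 0. Control spots were then left out, outlier spots (77 to 193 per array) were set to missing, and spots of a probe were averaged. Probes had to be well above background in Cy5 on every array of at least 1 of the 6 replicated groups, which 34805 probes were. For the 7717 genes with several probes the brightest probe on average was kept. Among genes called in a comparison, 4.35% to 24.7% of their other probes pointed the opposite way, with the lowest share in the pregnancy effect of P6 and the highest in that of P5. Probes were named through a RefSeq gene table, 22951 by accession, 6659 by symbol and 3109 by synonym, while 8455 kept the name in the files. In all, 23647 genes were tested, 17084 of them with a symbol of that table.

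Signal limits the precision here, as does the number of arrays. The median Cy5 intensity ran from 70.9 to 196 per array, against local backgrounds of 32 to 34.5, and 66.4% to 86.7% of probes were well above background in Cy5. The arrays lay on 5 slides and were scanned in 3 batches. Scan 1 held replicate 1 of virgin P4, P5 and P6 (slide 1) and both GFP arrays (slide 5). Scan 2 held replicate 2 of virgin P4, P5 and P6 and of pregnant P4 (slide 2) and of pregnant P5 and P6 (slide 4). Scan 3 held replicate 1 of the 3 pregnant populations (slide 3). Deviations from the group means of arrays with the same replicate number correlated at 0.31 to 0.679 over the 3 pairs of virgin groups and at 0.627 to 0.687 over the 3 pairs of pregnant groups. Across conditions the 9 pairs ran from -0.204 to 0.138. The numbers so pair the arrays within a condition, where arrays of one number shared a scan, and not across conditions. Scan 3 was made without the extended dynamic range, and its arrays had 111 to 236 saturated Cy5 spots against 0 to 15 on the others.

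Groups were taken from the labels. The design text sets P4 and GFPhi, the stem-cell-enriched populations, against P5, P6 and GFPlo, the depleted ones, in virgin and in pregnant mice. A first model gave each of these 4 cells a mean over all 14 arrays, with 10 residual degrees of freedom, and tested enriched minus depleted in each condition and the difference between both (an interaction). A second gave each of the 6 replicated groups a mean over 12 arrays, with 6 residual degrees of freedom. It tested the pairs of populations within a condition, the pregnancy effect in each population, and with an F test whether that effect differed among P4, P5 and P6. Both used lmFit and eBayes, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. GFPhi and GFPlo have 1 array each, so their difference carries no test. The labels do not say whether replicates came from separate animals, so every p-value measures only the spread between these samples, which may be technical.

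The comparisons, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes passed the threshold, had a symbol, were well above background in Cy5 on every array of the higher group and had no overlap between the arrays of both groups. Of these the 10 with the largest positive and the 10 with the largest negative differences were taken. The interaction has no single pair of groups, so its 16 named genes needed a symbol and detection in at least 1 cell. The F test gave its 10 smallest p-values, GFPhi minus GFPlo its 10 largest differences each way, and any member of a list may be named. Where a probe was not well above background, or was saturated, on every array of a group, the fold is a bound. It sets the mean of the brighter group against the higher of the array's lowest well-measured signal and the probe's own signal, per channel after loess and Aquantile, here of Cy5. It leaves out Cy3, so it is open to dye bias without dye swaps and can exceed the fold of the ratios, whose log2 difference is given beside it. Where only some arrays of a group were saturated, their number is given.

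The 22 gene lists were, with measured over listed members: basal and myoepithelial markers (17 of 17), stem-cell-associated genes (14 of 14), luminal progenitor markers (13 of 13), hormone-sensing luminal markers (14 of 15), general luminal and epithelial markers (16 of 16), milk and secretory genes (17 of 17), fatty acid and triglyceride synthesis (21 of 21), cholesterol synthesis (18 of 18), cell cycle (30 of 30), mesenchymal genes and those of the epithelial-mesenchymal transition (15 of 15), the Wnt pathway (32 of 32), the Notch pathway (18 of 18), basement membrane and its integrins (22 of 23), fibroblast (19 of 19), endothelial (15 of 15), pericyte (8 of 8), leukocyte (18 of 18), adipocyte (11 of 11), erythroid (5 of 7) and nerve and glial markers (8 of 8), early response and heat shock genes (15 of 16), and genes of the sorting antibodies (4 of 5). The last list was given as values only. For each of the other 21, calls were counted with the adjustment over all genes and adjusted over the list alone. Each was also compared with all other genes by limma's camera on the genes without missing values (142 left out) with a preset correlation of 0.01, adjusted over 252 pairs of list and comparison, and again with an estimated correlation. Of the 130 pairs past the threshold with the preset correlation, 30 passed with the estimated one. For GFPhi minus GFPlo the percentile of a list's median was taken among 10000 random lists of the same size, matched over 50 bins of intensity.

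The alternatives were no background correction, the scanner's log ratio, Aquantile scaling, median centring without loess, the series table, no filter, a filter in Cy3 too, all probes separately, the replicate number, slide or scan as a block, eBayes with trend and robust, only the arrays compared, each replicate left out, means over 8 groups, the fit without both GFP arrays, and camera with other settings. Chosen after seeing the data were normexp on the backgrounds as given, the replicate number as a block of its own in each condition, slide or scan as a block in camera, and the fits without the 3 arrays of scan 3. The pipeline was tested on simulated data with known changes, over 23505 genes. At a log2 change of 1 and 2 it recovered 43% and 75% of changed genes in enriched minus depleted of virgin mice, 26% and 75% in P4 minus P5 of virgin mice, and 27% and 79% in the pregnancy effect of P6. The other tools were data.table (version 1.17.8), jsonlite 2.0.0 and statmod 1.5.0, and Python 3.11.15 with matplotlib 3.10.9 for figures.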

Results

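The data are expression profiles of sorted mammary cell populations from FVB mice, virgin or pregnant, on 14 arrays. Stem cells were enriched in 2 ways. In wild-type mice, gates on the surface proteins CD24 and CD29 gave the populations P4, P5 and P6, with 2 arrays each from virgin and 2 each from pregnant mice. The labels describe both P4 and P5 as CD24-positive with high CD29, and P6 as CD24-low. They call P4 stem-cell-enriched, P5 enriched for luminal progenitors and P6 differentiated. The sorting genes, given at the end, differed between P4 and P5, so the gate named for P5 is uncertain. P4 minus P5 compares the populations as labelled. In virgin L2G85 mice, which carry a GFP reporter, lineage-negative cells with high (GFPhi) or low (GFPlo) GFP were sorted, with 1 array each. Values are log2 ratios of the sorted cells over a common reference RNA, and differences between groups are differences of these ratios. Correlations between arrays over all genes, which are not independent replicates, ran from 0.234 to 0.941, so no array ran against the others. No array repeated another.

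The first comparison asked what set the enriched populations (P4 and GFPhi, 3 arrays) apart from the depleted ones (P5, P6 and GFPlo, 5 arrays) in virgin mice. Genes of the basal, contractile layer of the gland were far higher in the enriched populations. Trp63, the transcription factor that marks basal epithelial cells, was 50.2-fold higher (log2 difference 5.65, SE 0.467, adjusted p = 3.72e-05), with a depleted mean of 1.13 ± 0.97 (SD, n = 5). Col17a1, a collagen of the hemidesmosomes, was at 7.50 ± 0.58 (n = 3) against 1.99 ± 0.80 (n = 5), 45.7-fold higher (adjusted p = 3.33e-05). The smooth muscle proteins Cnn1 (5.31), Tagln (5.03) and Acta2 (4.67) and the secreted Wnt or BMP antagonists Wif1 (4.85) and Sostdc1 (4.69) were among the 10 largest differences. The most negative difference of a named gene was that of Nupr1, a stress-induced nuclear protein, at -2.34 (SE 0.427, adjusted p = 0.014).

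Of 17 basal and myoepithelial markers, 13 were higher and 4 did not pass, with 16 higher when adjusted over the list alone. Their median difference was 3.40 (camera adjusted p = 9.59e-34), and the basal keratins Krt14 (8.57-fold higher, SE 0.493) and Krt5 (3.17, SE 0.588) were among them. Of 14 stem-cell-associated genes, 3 were higher and 11 did not pass (5 higher adjusted over the list alone; median 0.72; camera adjusted p = 1.39e-06). The Notch ligand Dll1 was 19.1-fold higher (4.26, SE 0.355), the R-spondin receptor Lgr5 10-fold higher (3.33, SE 0.277), and the transcription factor Bcl11b was higher by 2.33. Of 22 genes of the basement membrane and its integrins, 5 were higher and 17 did not pass (9 higher adjusted over the list alone; median 1.30; camera adjusted p = 3.18e-09), with the laminin chain Lama1 at 3.28. Of 32 Wnt pathway genes, 5 were higher and 27 did not pass (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0063, and adjusted p = 0.39 with an estimated correlation). No hormone-sensing luminal marker passed on its own, but the list lay lower with a median of -0.96 (camera adjusted p = 1.91e-05, and adjusted p = 0.192 with an estimated correlation). Markers of other cell types moved with the enriched populations too. The endothelial median was 0.86 (camera adjusted p = 5.97e-05, and adjusted p = 0.424 with an estimated correlation) and the fibroblast median -1.41 (camera adjusted p = 0.00539, and adjusted p = 0.715 with an estimated correlation).

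Limma called 384 of the genes tested, 359 higher and 25 lower in the enriched populations, 339 of them by at least 2-fold. With slide as a block 327 genes were called and with scan as a block 438, and the basal median was 3.44 and 3.42, against 3.01 to 4.05 within single slides or scans that held both classes. The count was 157 with median centring, 192 without replicate 1 and 186 without replicate 2 of virgin P4, and without either of these arrays Nupr1, Acta2 and Lama1 were no longer called. Krt5 lost its call without replicate 1 of virgin P4 or without GFPhi. With the scanner's log ratio or the series table Lgr5 and Lama1 were not called, nor was Bcl11b with median centring. Of the 20 named genes 15 kept their call with slide as a block. With means over the 8 groups, where differences among P5, P6 and GFPlo no longer add to the spread, it was 1589, of which 60.1% were higher against 93.5%.

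The same comparison in pregnant mice set P4 (2 arrays) against P5 and P6 (4 arrays). Basal genes again led. Trp63 was 37.6-fold higher, at 5.89 ± 0.47 (n = 2) against 0.66 ± 0.30 (n = 4; log2 difference 5.23, SE 0.553, adjusted p = 0.000279). Perp, a desmosome protein, differed by 5.28 (saturated on 1 of the 2 P4 arrays; adjusted p = 0.0788 with the replicate number as a block in each condition), Sostdc1 by 5.07, the intermediate filament protein Synm by 4.79 and the alkaline phosphatase Alpl by 4.71. Nupr1 again had the most negative difference of a named gene, -2.94 (SE 0.507, adjusted p = 0.00816), followed by Hacd4 (-2.33), which lost its call with median centring.

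Of the 17 basal markers, 8 were higher and 9 did not pass, while all 17 were higher when adjusted over the list alone (median 3.13; camera adjusted p = 2.71e-22). The oxytocin receptor Oxtr, through which myoepithelial cells contract at milk let-down, was higher by 4.01 and the smooth muscle actin Actg2, saturated on 1 of the 2 P4 arrays, by 3.84, and neither passed with slide as a block. Of 14 stem-cell-associated genes, 2 were higher and 12 did not pass, as was the count adjusted over the list alone (camera adjusted p = 0.000141), with Dll1 21.1-fold higher (4.40). Of 22 basement membrane genes, 5 were higher and 17 did not pass (9 adjusted over the list alone; median 1.59; camera adjusted p = 1.49e-09). Of 18 Notch pathway genes, 4 were higher and 14 did not pass (6 adjusted over the list alone; camera adjusted p = 5.36e-05, and adjusted p = 0.089 with an estimated correlation). The Wnt list had 7 of 32 higher and 25 that did not pass, also 7 adjusted over the list alone (camera adjusted p = 5.11e-05, and adjusted p = 0.174 with an estimated correlation). Endothelial markers lay higher in the same arrays, with 1 of 15 past the threshold, 10 adjusted over the list alone, and a median of 1.80 (camera adjusted p = 1.43e-08, and adjusted p = 0.234 with an estimated correlation). Early response and heat shock genes also lay higher, with 1 of 15 past the threshold and 4 adjusted over the list alone (median 0.99, or 1.59 with slide as a block; camera adjusted p = 9.16e-06, and adjusted p = 0.24 with an estimated correlation). So did adipocyte markers, with 1 of 11 past the threshold, Lep, which was also the count adjusted over the list alone (median 1.20, or 1.89 with slide as a block; camera adjusted p = 4.73e-05, and adjusted p = 0.0751 with an estimated correlation). The fibroblast median was -2.00 (camera adjusted p = 0.0333, and adjusted p = 0.779 with an estimated correlation, 0.112 with slide, 0.0771 with scan and 0.0864 with the replicate number in each condition as a block, and 0.109 without scan 3).

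In all, 590 genes were called, 534 higher and 56 lower. With slide as a block 118 were called, with 3 of the 20 named genes (Nupr1 not), and with scan as a block 767 (Perp not), and the basal median was 2.38 and 3.13, against 2.38 to 4.58 within batches. The count was 235 with only the arrays compared, 177 without the 3 arrays of scan 3, 295 without replicate 1 and 269 without replicate 2 of pregnant P4 (Nupr1 and Perp not called in any of these 4), and 2966 with means over the 8 groups, of which 58.8% were higher against 90.5%.

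Whether the enriched-minus-depleted difference itself changed with pregnancy was tested as an interaction, which called 23 genes, 16 with a larger and 7 with a smaller difference in pregnant mice. Lep, which encodes leptin, had the largest interaction, 3.78 (SE 0.275, adjusted p = 0.000304). Its mean was 4.35 in the enriched arrays of pregnant mice against 0.26 in those of virgin mice and 0.00 and 0.30 in the depleted arrays. Lgr5 had the most negative one, -2.87 (SE 0.43, adjusted p = 0.03), with means of 4.38 in the enriched arrays of virgin mice, 0.57 in those of pregnant mice and 1.05 and 0.11 in the depleted arrays. Ppm1l (2.95), Amhr2 (2.47), Pdzd3 (2.36), Abcg5 (-2.09) and Foxj1 (-1.95) also passed. The early response and heat shock list shifted by 1.61 (0.99 without scan 3; camera adjusted p = 4.79e-10, and adjusted p = 0.0999 with an estimated correlation) and the adipocyte list by 1.12 (1.89 with slide as a block and 0.84 without scan 3; camera adjusted p = 6.53e-06), which was past the threshold with an estimated correlation too (adjusted p = 0.0477).

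With the scanner's log ratio and with the series table limma called 0 genes, and 777 and 784 had an unadjusted p under 0.05, against 1003 here. Each number is under the 1 in 20 of the 23646 genes tested that chance alone would give. The count was 13 with median centring, which moved the median over all genes to 0.26, and 2 with a filter in Cy3. Slide as a block gave 7 genes, 2 of them among the 23, and with scan as a block 20. Lgr5 and Ppm1l lost their call with either, and Amhr2, Abcg5 and Foxj1 with slide as a block. The replicate number as a block in each condition gave 20 genes, 14 of them among the 23, without Lgr5 and Ppm1l. Lgr5 also lost it in 12 of the 14 fits that left out 1 array, all but those without virgin P5 replicate 1 or GFPlo. It was 8 without scan 3, 341 with means over the 8 groups, 13 without replicate 1 and 11 without replicate 2 of virgin P4. Only scan 2 held arrays of all 4 cells (6 arrays). Within it, on arrays that also entered the test, Lep was at 4.30 and Lgr5 at -2.78, and the adipocyte and early response medians were 0.59 and 1.01.

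**Figure D1:**
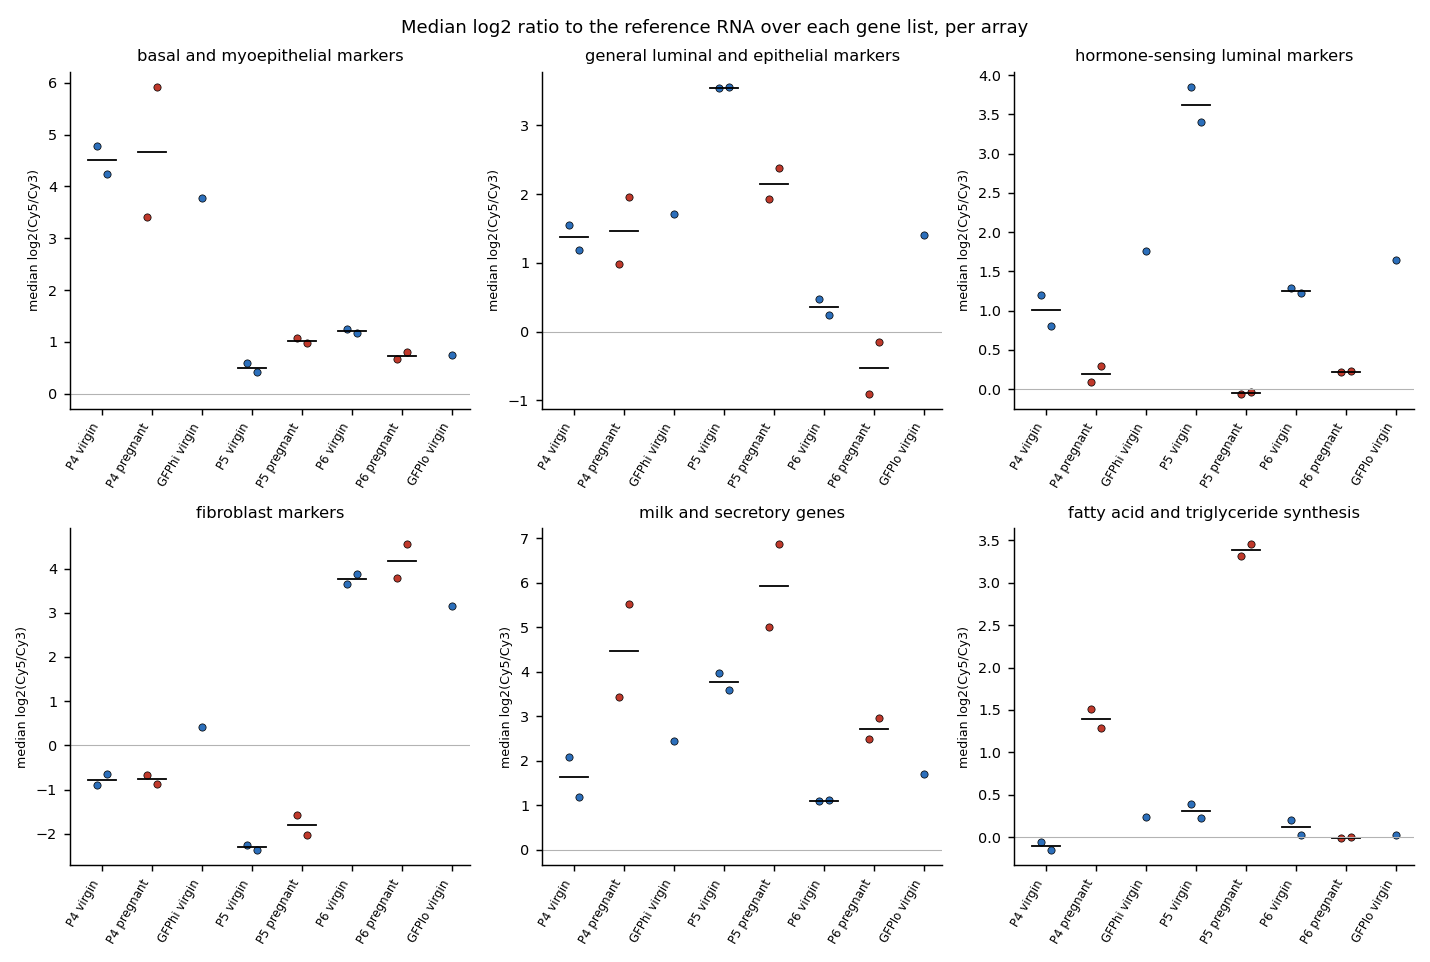
The median log2 ratio over the reference (vertical axis) of 6 gene lists is plotted for each array by population (horizontal axis), with virgin arrays in blue, pregnant arrays in red and a bar at the mean of 2 replicates. Basal markers sit at 4.79 and 4.23 in P4 of virgin mice, 3.41 and 5.91 in P4 of pregnant mice and 3.77 in GFPhi, and at 1.25 or less elsewhere, and fibroblast markers sit highest in P6 among the wild-type populations.

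Pairs of populations were then compared within the virgin wild-type mice, 2 arrays against 2. Between P4 and P5, contractile and basal genes were higher in P4. Myl9, a light chain of smooth muscle myosin, was at 4.62 ± 0.23 against -1.87 ± 0.57 (SD, n = 2), 90.1-fold higher (log2 difference 6.49, SE 0.836, adjusted p = 0.00152), followed by Tagln (6.39), Cnn1 (5.91) and Trp63 (5.87, SE 0.389). In P5 the luminal keratin Krt18 (-3.60, adjusted p = 0.00195), the tryptophan-degrading enzyme Ido1 (-4.11, adjusted p = 9.89e-06) and the membrane protein Prom1 (-3.40) were higher. Myl1 (-4.98), Tnnc2 (-4.31), Myh4 (-4.05) and Mylpf (-3.87), genes of fast skeletal muscle, were also higher in P5, and no list of muscle markers had been fixed.

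Of the basal markers, 16 of 17 were higher in P4 and 1 did not pass (17 adjusted over the list alone; median 4.80; camera adjusted p = 3.86e-16, and adjusted p = 0.0855 with an estimated correlation). Of 14 hormone-sensing luminal markers, 12 were lower in P4, also 12 adjusted over the list alone, and 2 did not pass (median -2.57; camera adjusted p = 6.76e-14). They held the receptors of estrogen (Esr1, -2.78), progesterone (Pgr, -2.33) and prolactin (Prlr, -2.70) and the growth factor Areg (-3.20). Of 16 general luminal markers, 9 were lower and 7 did not pass (13 adjusted over the list alone; camera adjusted p = 1.38e-09, and adjusted p = 0.203 with an estimated correlation). Of 14 stem-cell-associated genes, 8 were higher and 1 lower in P4, and 10 and 2 adjusted over the list alone (camera adjusted p = 8.81e-07, and adjusted p = 0.101 with an estimated correlation). Lgr5 was 14.4-fold and the transcription factor Snai2 28.7-fold higher. Of 22 basement membrane genes, 14 were higher and 8 did not pass (18 adjusted over the list alone; camera adjusted p = 4.14e-14), with the collagen IV chain Col4a1 24.9-fold higher. The Wnt list had 15 of 32 higher and 3 lower, also when adjusted over the list alone (camera adjusted p = 2.86e-05). Of 19 fibroblast markers 8 were higher and 1 lower in P4, and 10 and 1 adjusted over the list alone (median 1.01; camera adjusted p = 2.64e-06, and adjusted p = 0.103 with an estimated correlation). Of 15 endothelial markers 5 were higher and 10 did not pass (11 adjusted over the list alone; median 2.00; camera adjusted p = 2.26e-06, and adjusted p = 0.39 with an estimated correlation). Of 8 pericyte markers 3 were higher, also adjusted over the list alone (median 1.40; camera adjusted p = 0.0204, and adjusted p = 0.626 with an estimated correlation, 0.0561 with slide as a block).

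Between P4 and P6, collagens and other genes of fibroblasts were far higher in P6. The fibrillar collagen Col3a1 was at -1.41 ± 0.13 in P4 and 5.86 ± 0.26 in P6 (SD, n = 2), a 154-fold difference (log2 difference -7.27, SE 0.817, adjusted p = 0.000685), followed by Col1a2 (-6.94), Efemp1 (-6.78), Col1a1 (-6.70) and Lum (-6.51). Pdgfra, a receptor of stromal cells, was 47.4-fold lower in P4. Of 19 fibroblast markers 18 were lower in P4, also adjusted over the list alone (median -3.96; camera adjusted p = 4.76e-27), and of 15 mesenchymal genes 9 were lower, again also adjusted over the list alone (median -2.64; camera adjusted p = 6.05e-08). Higher in P4 were the protease inhibitor Slpi (6.28), Perp (6.0), Trp63 (5.79) and the integrin Itga6 (5.05), and 14 of 17 basal markers (17 adjusted over the list alone; median 3.0; camera adjusted p = 6e-14, and adjusted p = 0.101 with an estimated correlation). Of the general luminal markers 6 of 16 were higher in P4 and 10 did not pass (10 higher adjusted over the list alone; median 1.25; camera adjusted p = 9.88e-06, and adjusted p = 0.361 with an estimated correlation). The pericyte median was -1.10 (camera adjusted p = 0.00115, and adjusted p = 0.441 with an estimated correlation). The endothelial one was 0.82 (camera adjusted p = 0.0301, and adjusted p = 0.704 with an estimated correlation). The early response one was -0.79 (camera adjusted p = 0.0135, and adjusted p = 0.622 with an estimated correlation).

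Between P5 and P6, keratins of luminal cells were higher in P5 and stromal genes again in P6. Krt18 was at 4.22 ± 0.43 in P5 (SD, n = 2), 34.6-fold above P6 (log2 difference 5.11, SE 0.443, adjusted p = 0.00019), and Krt8, its partner, at 3.82 ± 0.70 against -1.07 ± 0.10, 29.7-fold higher. Col3a1 was 298-fold lower in P5 (-8.22, SE 0.817, adjusted p = 0.000199). Of 16 general luminal markers 14 were higher in P5, also adjusted over the list alone (median 3.16; camera adjusted p = 3.43e-12, and adjusted p = 0.151 with an estimated correlation), with the adhesion proteins Epcam (3.74) and Cdh1 (3.73) among them. Of the hormone-sensing markers 10 of 14 were higher and 1 lower in P5 (10 and 3 adjusted over the list alone; median 2.15; camera adjusted p = 1.91e-06). Of 13 luminal progenitor markers 5 were higher, also adjusted over the list alone, and 8 did not pass, with the transcription factor Elf5 (3.04), the receptor Kit (2.76) and Cd14 (3.01) among them (camera adjusted p = 0.00683, and adjusted p = 0.491 with an estimated correlation). All 19 fibroblast markers were lower in P5 (median -5.83; camera adjusted p = 1.07e-25). So were 11 of 15 mesenchymal genes, with 1 higher (median -3.91; camera adjusted p = 8.84e-10), and the counts of both lists were the same adjusted over the list alone. Of 8 pericyte markers 4 were lower in P5 (6 adjusted over the list alone; median -2.55; camera adjusted p = 0.000181, and adjusted p = 0.39 with an estimated correlation). The endothelial median was -0.93 (camera adjusted p = 0.00607). The early response one was -0.79 (camera adjusted p = 0.0322). Both had an adjusted p = 0.63 with an estimated correlation.

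P4 minus P5 called 2685 genes (1552 higher, 1133 lower), P4 minus P6 2440 (1153 and 1287) and P5 minus P6 3814 (1725 and 2089). With slide as a block the counts were 5513, 4976 and 6580, with scan as a block 5731, 5167 and 6851, and with median centring 1287, 1024 and 2143, which put 42.9% of the P4-P5 calls higher against 57.8%. The blocked medians were the same. Within slides, the basal median of P4 minus P5 was 4.70 to 4.89, the hormone-sensing one -2.56 to -2.41, the fibroblast one of P4 minus P6 -4.07 to -3.86, and the general luminal one of P5 minus P6 2.91 to 3.31. With backgrounds as given the shares of higher calls in P4 minus P6 and P5 minus P6 were 66% and 56.2% against 47.3% and 45.2%. P4 minus P5 called 1444 and 1293 genes without virgin P4 replicate 1 or 2 and 1535 and 1415 without virgin P5 replicate 1 or 2. P4 minus P6 called 1405 and 1299 without virgin P4 replicate 1 or 2, and P5 minus P6 called 2481 without virgin P5 replicate 2. The P4-P5 call of Cnn1 was lost without P4 replicate 1 or P5 replicate 2, that of Esr1 without either P4 array or P5 replicate 1, and also without scan 3. That of Cd14 between P5 and P6 was lost without any 1 of the 4 arrays. The scanner's log ratio and the series table ended the P4-P5 call of Myh4 and the P5-P6 calls of Elf5 and Kit.

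In pregnant mice the same pairs were compared, again 2 arrays against 2, and genes of lipid synthesis were higher in P5 than in both other populations. Between P4 and P5, the serine protease Prss23, saturated on 1 of the 2 P4 arrays, was 86-fold higher in P4 (log2 difference 6.43, SE 0.894, adjusted p = 0.00134). Snai2 was 39.3-fold higher, at 3.42 ± 0.14 against -1.88 ± 0.64 (SD, n = 2; SE 0.312, adjusted p = 3.1e-05), and Trp63 35-fold higher. Acaca, which makes malonyl-CoA for fatty acid synthesis, was lower in P4 by -2.60 (adjusted p = 0.000462), a call lost with median centring. Of 21 genes of fatty acid and triglyceride synthesis 17 were lower in P4 and 4 did not pass (18 lower and 1 higher adjusted over the list alone; median -2.07; camera adjusted p = 3.7e-10). Of 17 milk and secretory genes 7 were lower, also adjusted over the list alone (camera adjusted p = 0.000666, and adjusted p = 0.61 with an estimated correlation). Higher in P4 were 12 of 17 basal markers, also adjusted over the list alone (median 2.89; camera adjusted p = 3.18e-09, and adjusted p = 0.191 with an estimated correlation), and 18 of 22 basement membrane genes, likewise 18 (median 2.35; camera adjusted p = 6.83e-12). So were 16 of 32 Wnt genes (18 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.87e-07) and 9 of 18 Notch genes, also adjusted over the list alone (camera adjusted p = 0.00015, and adjusted p = 0.205 with an estimated correlation). Of 15 endothelial markers 9 were higher and 1 lower in P4 (13 and 1 adjusted over the list alone; median 1.98; camera adjusted p = 0.000139, and adjusted p = 0.513 with an estimated correlation). The fibroblast median was 0.59 (camera adjusted p = 0.00298, and adjusted p = 0.298 with an estimated correlation). The adipocyte one was 0.90, or 1.67 with slide as a block (camera adjusted p = 0.0368, and adjusted p = 0.267 with an estimated correlation).

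Between P4 and P6 of pregnant mice, Perp was 124-fold higher in P4 (log2 difference 6.95, SE 0.262, adjusted p = 4.31e-06), Krt8 55.3-fold and Itga6 52.9-fold. Perp and Krt8 were saturated on 1 of the 2 P4 arrays and Mmp3 on 1 of the 2 P6 arrays, where a signal reads too low. The matrix-degrading protease Mmp3 was 248-fold lower, at -1.92 ± 0.45 against 6.03 ± 1.21 (SD, n = 2; SE 0.474, adjusted p = 2.49e-05), and Pdgfra 132-fold lower. Of 17 basal markers 13 were higher (17 adjusted over the list alone; median 3.62; camera adjusted p = 2.03e-14, and adjusted p = 0.0999 with an estimated correlation), and of 19 fibroblast markers 18 were lower, also adjusted over the list alone (median -4.59; camera adjusted p = 1.44e-26). Of 21 fatty acid genes 8 were higher in P4 and 13 did not pass (14 adjusted over the list alone; median 1.16; camera adjusted p = 7.23e-08). Of 16 general luminal markers 10 were higher (11 adjusted over the list alone; median 2.09; camera adjusted p = 3.29e-09, and adjusted p = 0.207 with an estimated correlation). Adipocyte markers, with 1 of 11 past the threshold, also adjusted over the list alone, had a median of 1.44 in the same arrays, or 0.80 without scan 3 (camera adjusted p = 0.00194, and adjusted p = 0.107 with an estimated correlation). Of 15 endothelial markers 4 were higher (11 and 1 lower adjusted over the list alone; median 1.65; camera adjusted p = 0.000139, and adjusted p = 0.513 with an estimated correlation). Of 15 mesenchymal genes 8 were lower and 2 higher (8 and 3 adjusted over the list alone; median -1.71; camera adjusted p = 4.36e-05). The early response median was 0.57, or 0.99 with slide as a block (camera adjusted p = 0.0395, and adjusted p = 0.634 with an estimated correlation, 0.203 without scan 3).

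Between P5 and P6 of pregnant mice, the fatty acid-activating enzyme Acsl1 was 71.8-fold higher in P5 (log2 difference 6.17, SE 0.347, adjusted p = 8.63e-06), the glycolytic Aldoc 63.7-fold, the desaturase Scd1, saturated on 1 of the 2 P5 arrays, 25.1-fold and Acaca 22.1-fold. Of 21 fatty acid genes 18 were higher in P5 (20 adjusted over the list alone; median 2.94; camera adjusted p = 1.68e-13). Of 18 genes of cholesterol synthesis 10 were higher (12 adjusted over the list alone; median 1.26; camera adjusted p = 0.000137, and adjusted p = 0.1 with an estimated correlation), and of 17 milk genes 9 were higher (10 adjusted over the list alone; median 2.73; camera adjusted p = 0.000144, and adjusted p = 0.557 with an estimated correlation). Of 30 cell cycle genes 9 were higher in P5 and 21 did not pass (14 adjusted over the list alone; median 1.29; camera adjusted p = 4.1e-05, and adjusted p = 0.63 with an estimated correlation). All 19 fibroblast markers were lower, with Mmp3, itself not on the list, 214-fold lower (median -6.10; camera adjusted p = 5.15e-20), and so were 10 of 15 mesenchymal genes (camera adjusted p = 4.32e-08); both counts were the same adjusted over the list alone. Of 16 general luminal markers 12 were higher in P5 (14 adjusted over the list alone; median 2.93; camera adjusted p = 1.86e-07, and adjusted p = 0.269 with an estimated correlation). Of 8 pericyte markers 5 were lower (6 adjusted over the list alone; median -2.21, or -3.42 without scan 3; camera adjusted p = 0.000408, and adjusted p = 0.4 with an estimated correlation). The early response median was -0.63, or -1.11 without scan 3 (camera adjusted p = 0.0301, and adjusted p = 0.63 with an estimated correlation).

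P4 minus P5 called 5337 genes in pregnant mice (2755 higher, 2582 lower), P4 minus P6 2857 (1465 and 1392) and P5 minus P6 6363 (3244 and 3119). With slide as a block the counts were 6857, 4078 and 10219, with scan as a block 9747, 5770 and 10470, and with only the arrays compared 2869, 917 and 3549. Median centring gave 2405, 1646 and 2774, put 77.4% and 70% of the P4-P5 and P4-P6 calls higher against 51.6% and 51.3%, and moved the median over all genes of P4 minus P6 to 0.16. The scanner's log ratio moved that of P4 minus P5 to -0.17 and that of P5 minus P6 to 0.17. The basal median of P4 minus P5 was 2.15 and 2.89 with slide and scan as a block and 2.24 to 4.52 within batches, and that of P4 minus P6 2.33, 3.62 and 2.69 to 4.49. The fatty acid median of P4 minus P5 was -2.07 with either block and -2.23 to -2.02 within batches, and that of P5 minus P6 2.94 with either block and 2.69 to 3.01. The fibroblast median of P4 minus P6 was -4.70 and -4.59 with slide and scan as a block and -4.98 to -4.26 within batches. P4 minus P5 called 3404 genes with backgrounds as given, 3389 without pregnant P4 replicate 1 and 3210 without pregnant P5 replicate 2. P4 minus P6 shared 756 higher and 911 lower genes with virgin mice, against 71.4 and 75.8 for independent lists, and 13 opposed. For P4 minus P5 these were 1056 and 371, against 181 and 124, and 152 opposed. For P5 minus P6 they were 842 and 1603, against 237 and 276, and 128 opposed.

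**Figure D2:**
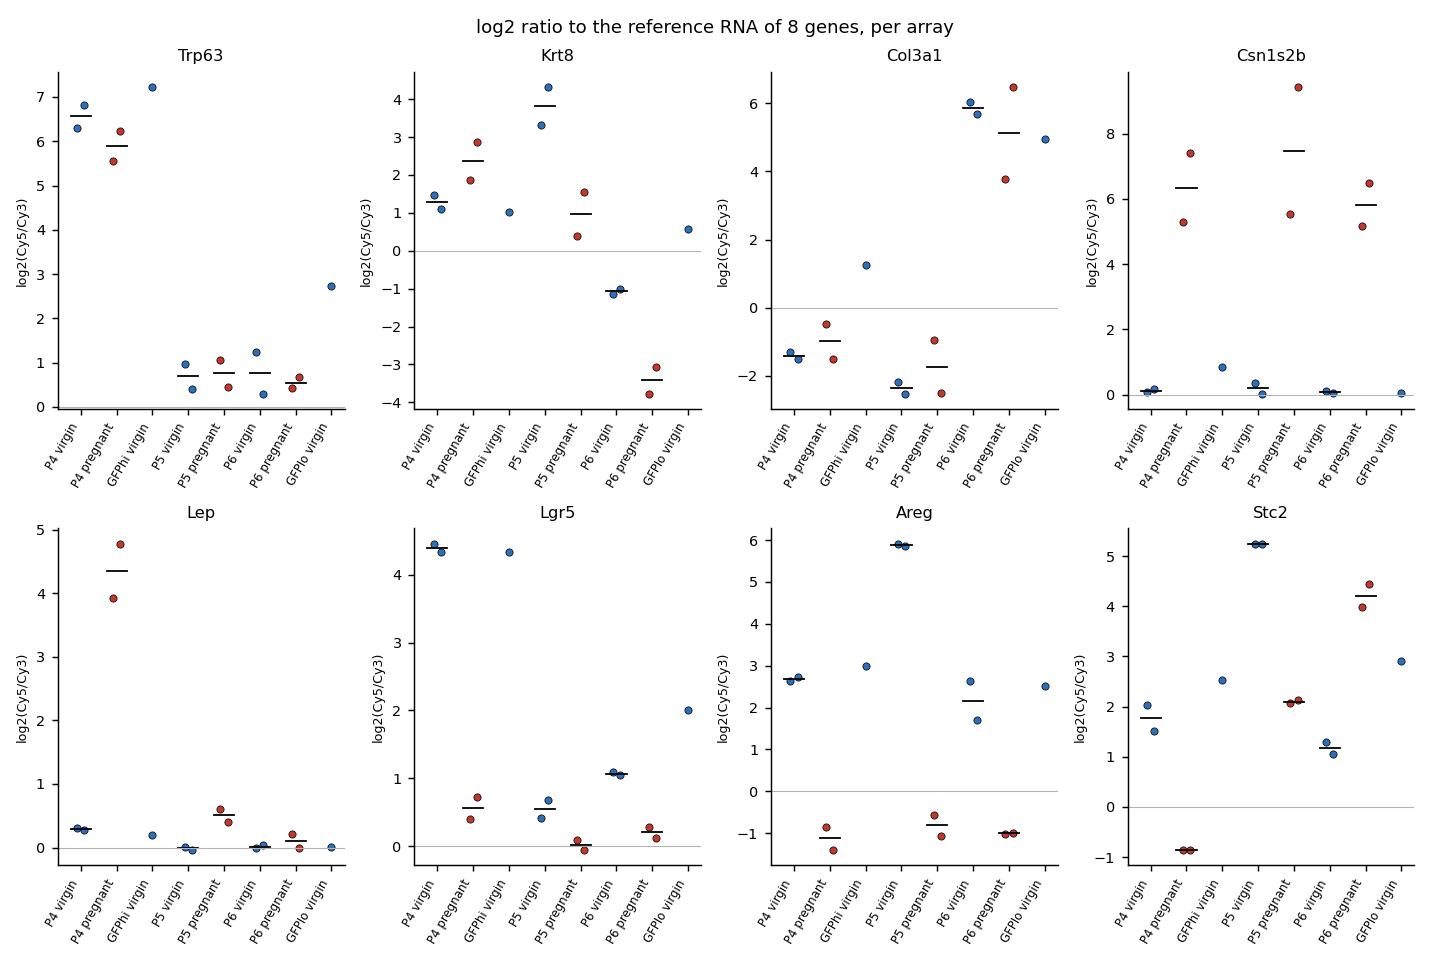
The log2 ratio over the reference (vertical axis) of 8 genes is plotted for each array by population (horizontal axis), with virgin arrays in blue, pregnant arrays in red and a bar at the mean of 2 replicates. Lep lies at 3.92 and 4.78 in P4 of pregnant mice and at most at 0.61 elsewhere, Lgr5 is highest in P4 and GFPhi of virgin mice, and Stc2 is higher in pregnant than in virgin mice in P6 and lower in P4 and P5.

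The pregnancy effect was taken within each population, 2 arrays against 2. In P4, genes of milk and fat synthesis rose, and the receptor Lgr5 and the growth factor Areg fell. The casein Csn1s2b rose 74.8-fold, from 0.13 ± 0.08 to 6.35 ± 1.49 (SD, n = 2; log2 difference 6.23, SE 1.13, adjusted p = 0.0242), and the fatty acid-binding protein Fabp3 rose 75-fold (SE 0.97, adjusted p = 0.0137). Both were saturated on 1 of the 2 pregnant arrays, and Csn1s2b was well above background on 1 of the 2 virgin arrays. Csn1s2b also stood at 5.532 and 9.423 in pregnant P5 and at 5.171 and 6.48 in pregnant P6. Whether RNA from cells of the P5 type adds to the rises of milk and fat synthesis genes in P4 was not tested. Scd1 rose 20.1-fold (SE 0.311, adjusted p = 0.000641) and Lep 16.6-fold, from 0.29 ± 0.02 to 4.35 ± 0.61 (SE 0.247, adjusted p = 0.000376). Lgr5 fell 14.2-fold, to 0.57 ± 0.23 (log2 difference -3.83, SE 0.16, adjusted p = 5.8e-05), Areg by 3.81 (at least 14.4-fold in Cy5 alone) and the protease Pappa, which frees insulin-like growth factors, by 3.64 on the log2 scale. Of 21 fatty acid genes 9 rose and 12 did not pass (15 adjusted over the list alone; median 1.19; camera adjusted p = 2.41e-15), and of 18 cholesterol genes 4 rose (11 adjusted over the list alone; median 1.20; camera adjusted p = 1.84e-10). Of 17 milk genes 5 rose and 1 fell (8 and 1 adjusted over the list alone; median 1.66, or 2.74 with slide and 2.53 with scan as a block; camera adjusted p = 5.47e-06, and adjusted p = 0.435 with an estimated correlation). Of 14 hormone-sensing markers 4 fell and 1 rose (5 and 1 adjusted over the list alone; median -0.70, or -0.42 with scan as a block; camera adjusted p = 0.0036, and adjusted p = 0.156 with an estimated correlation, 0.0628 without scan 3). Adipocyte markers moved with these genes, with 1 of 11 past the threshold, 2 adjusted over the list alone, and a median of 1.46 (camera adjusted p = 0.000332, and adjusted p = 0.0767 with an estimated correlation). That median was 0.29 with slide (adjusted p = 0.0046) and 0.77 with scan as a block (adjusted p = 0.00419), 0.15 without scan 3 (adjusted p = 0.00409) and 0.37 within scan 2. The basal list, with no call, had a median of -0.31 (camera adjusted p = 0.623), which turned to 0.89 with slide as a block (adjusted p = 0.000104), 0.94 without scan 3 (adjusted p = 0.000142) and 1.08 within scan 2.

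In P5, milk and lipid genes rose and hormone-sensing genes fell. Csn1s2b rose 156-fold, to 7.48 ± 2.75 (SD, n = 2; log2 difference 7.29, SE 1.13, adjusted p = 0.00281), and the whey protein Wap rose by 5.41 on the log2 scale (at least 1270-fold in Cy5 alone; adjusted p = 0.0195, not called without either virgin array or pregnant replicate 2). The glycine-degrading enzyme Gldc rose 116-fold, the lipoprotein lipase Lpl 104-fold, Scd1 40.6-fold and Acaca 26.2-fold. Wap was saturated on both pregnant arrays and Csn1s2b, Lpl and Scd1 on 1 of the 2, and the log2 Cy3 signal of Wap was 6.64 to 6.88 on virgin and 7.38 to 11.97 on pregnant arrays, although the reference RNA was the same, so ratios of such genes understate the change. The growth factor Ptn fell 205-fold, from 6.28 ± 0.30 to -1.40 ± 0.42 (log2 difference -7.68, SE 0.363, adjusted p = 1.22e-05), Areg by 6.70, Foxa1 by 4.11, Prom1 by 4.51 and Pgr by 2.80 on the log2 scale. These 4 were not well above background on either pregnant array, and in Cy5 alone their falls were at least 310-fold, 46.3-fold, 21.6-fold and 6.87-fold. Of 21 fatty acid genes 18 rose and 1, the acyltransferase Dgat2 (-3.96), fell, the same counts as adjusted over the list alone (median 2.98; camera adjusted p = 4.7e-14). Of 14 hormone-sensing markers 12 fell, also adjusted over the list alone (median -3.07; camera adjusted p = 2.54e-12). Of 17 milk genes 8 rose and 1, the water channel Aqp5, fell, the same counts as adjusted over the list alone (median 1.90, or 3.12 with the Cy5 bounds, 3.79 with slide and 3.24 with scan as a block and 3.27 without scan 3; camera adjusted p = 0.00039, and adjusted p = 0.589 with an estimated correlation). Of 18 cholesterol genes 9 rose (12 adjusted over the list alone; median 1.41; camera adjusted p = 8.46e-06, and adjusted p = 0.0722 with an estimated correlation). Of 16 general luminal markers 8 fell and 1 rose (9 and 1 adjusted over the list alone; median -1.38, or -0.90 without scan 3; camera adjusted p = 0.000509, and adjusted p = 0.488 with an estimated correlation, 0.0712 with slide as a block), with Krt8 at -2.84. Of 17 basal markers 2 rose, also adjusted over the list alone (median 1.12; camera adjusted p = 0.0264, and adjusted p = 0.63 with an estimated correlation). Of 15 early response and heat shock genes 7 fell (8 adjusted over the list alone; median -1.44; camera adjusted p = 0.000144, and adjusted p = 0.39 with an estimated correlation), Egr1 by 2.38 and Jun by 2.35 on the log2 scale. Jun lost its call without any 1 virgin P4 or P5 array or pregnant P5 replicate 1, and Dgat2 without virgin P5 replicate 1 or pregnant P5 replicate 2.

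In P6 few genes passed. The hormone Stc2 rose 8.2-fold, to 4.21 ± 0.32 (SD, n = 2; log2 difference 3.04, SE 0.207, adjusted p = 0.00226), the retinal-oxidizing enzyme Aldh1a1 6.59-fold (SE 0.164, adjusted p = 0.00226) and the collagen cross-linking enzyme Lox by 2.30. Areg fell by 3.17 (at least 8.95-fold in Cy5 alone) and Ptn by 3.36 on the log2 scale. Without scan 3 Stc2, Lox, Areg and Ptn were not called, nor was Areg without pregnant P6 replicate 1 or Ptn without either virgin P4 array or virgin P6 replicate 1. No milk gene passed over all genes, while 4 were higher and 1 lower when adjusted over the list alone (median 1.31; camera adjusted p = 0.000203, and adjusted p = 0.568 with an estimated correlation). Of 16 general luminal markers 1 fell (8 adjusted over the list alone; median -1.30, or -0.79 with scan as a block and -0.74 without scan 3; camera adjusted p = 3.29e-09, and adjusted p = 0.207 with an estimated correlation). Of 14 hormone-sensing markers 1 rose and 1 fell (1 and 8 adjusted over the list alone; median -0.66; camera adjusted p = 5.72e-07). The early response list had no call (4 lower adjusted over the list alone; median -1.22, or -0.71 with scan as a block and -0.72 without scan 3; camera adjusted p = 6.59e-10, and adjusted p = 0.156 with an estimated correlation). Neither had the Wnt list (3 lower adjusted over the list alone; median -0.46, or -0.24 with slide and -0.23 with scan as a block and -0.27 without scan 3; camera adjusted p = 0.000125, 0.0765 with slide as a block). Of 19 fibroblast markers 1 rose (5 adjusted over the list alone; median 0.50; camera adjusted p = 0.000397, and adjusted p = 0.207 with an estimated correlation). The endothelial median was -0.53 (camera adjusted p = 0.0063, and adjusted p = 0.63 with an estimated correlation). It turned to 0.28 with slide as a block (adjusted p = 0.141) and 0.033 without scan 3 (adjusted p = 0.667).

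Pregnancy changed 885 genes in P4 (351 up, 534 down), 5062 in P5 (2538 up, 2524 down) and 44 in P6 (11 up, 33 down). With slide as a block these were 1244, 3409 and 9, with 0 of the 44 in P6 shared (Stc2 at 3.03, adjusted p = 0.0583), and with scan as a block 1747, 8387 and 142. With only the arrays compared limma called 0, 3336 and 0 genes, with 3854 in P4 and 1042 in P6 at an unadjusted p under 0.05. That of P6 is under the 1 in 20 that chance alone would give. The fatty acid median of P4 was 1.23 and 1.35 with slide and scan as a block and 1.18 within scan 2, and that of P5 3.06, 2.87 and 2.93. The hormone-sensing median of P5 was -3.09, -2.88 and -2.98, and the milk median of P6 2.04, 1.89 and 1.80. Without scan 3, 541 genes were called in P4 (52.9% up against 39.7%) and 8 in P6. The P4 count was 204 and 157 without virgin P4 replicate 1 or 2 and 336 without pregnant P4 replicate 1 (482 without replicate 2), where 10 of the 20 named genes kept their call throughout (Csn1s2b and Fabp3 not). The P5 count was 2373 and 3203 without virgin P5 replicate 1 or 2 and 3325 without pregnant P5 replicate 2.

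The P6 count was 18 without either virgin P4 array, 26 without either virgin P5 array, 28 and 21 without virgin P6 replicate 1 or 2, and 27 and 78 without pregnant P6 replicate 1 or 2, and 5 of the 20 named genes kept their call throughout. The P4 count was 190 with median centring (56.3% up), which moved the median over all genes to 0.15. The P5 count was 2421 with median centring (27.8% up against 50.1%). The P6 count was 17 with the scanner's log ratio, 25 with a filter in Cy3, 20 with trend and robust, 6 with median centring and 8 with backgrounds as given, where all 8 rose, while 42.3% rose with scan as a block and 35.5% with the series table, against 25%.

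The effect in P4 and in P5 shared 143 genes that rose and 218 that fell, against 37.7 and 57 for independent lists, and 62 moved in opposite directions. Arrays of P4 and P5 with the same number share a scan, and their deviations correlated at 0.447 in virgin and 0.687 in pregnant mice, so part of the excess may come from shared batches. With scan as a block 383 and 385 were shared (167 and 141 for independent lists), and without scan 3 141 and 99 (34.3 and 21.7). Slide as a block ties both effects to pregnant P4 replicate 2 and is no test. Whether the pregnancy effect differed among the 3 populations was tested with an F test, which called 1877 genes. Stc2 fell by 2.63 in P4 and 3.14 in P5 on the log2 scale but rose by 3.04 in P6 (adjusted p from 0.000172 to 0.00023 for the 10 leading genes). The milk transporter Abcg2 differed by 1.51, 5.84 and 0.08 in P4, P5 and P6, the growth factor Egf by 1.56, 4.72 and 0.46, Ido1 by -2.11, -5.78 and -1.53, and Prom1 by -1.06, -4.51 and -0.70. Of 21 fatty acid genes 14 passed the F test (19 adjusted over the list alone), of 14 hormone-sensing markers 7 (10), of 18 cholesterol genes 6 (11), of 16 general luminal markers 6 (8), of 32 Wnt genes 8 (11), of 14 stem-cell-associated genes 4 (5) and of 17 milk genes 3 (3). It called 5146 genes with slide and 6405 with scan as a block. The count was 427 with median centring, 1055 with backgrounds as given and 1186 without scan 3. It was 1077 and 1028 without virgin P4 replicate 1 or 2, 794 and 944 without virgin P5 replicate 1 or 2, and 1251 and 1094 without pregnant P5 replicate 1 or 2.

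**Figure D3:**
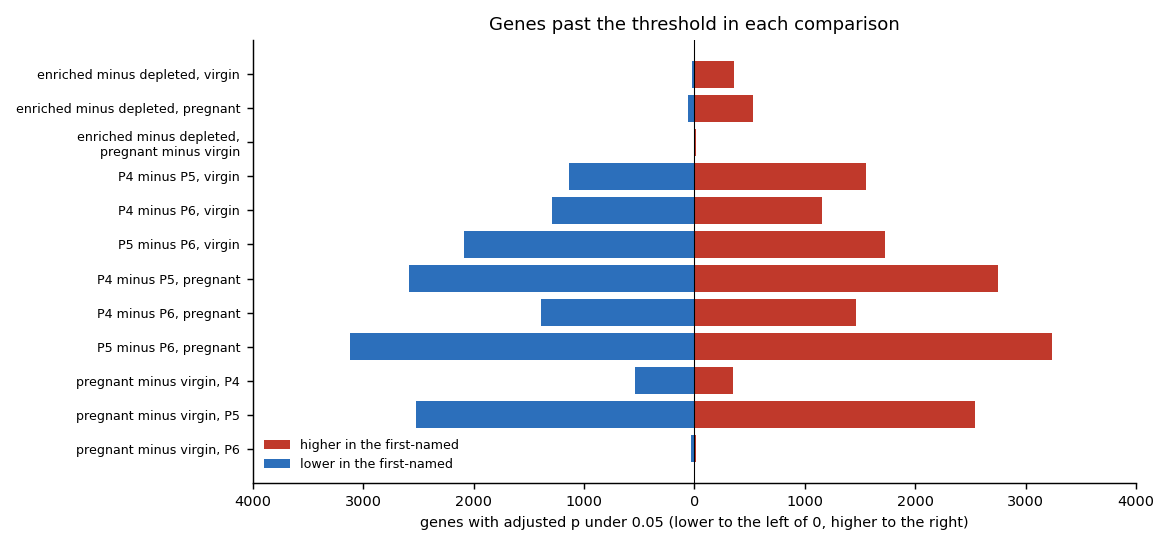
The number of genes past the threshold is plotted for each tested comparison, with genes higher in the first group in red and lower in blue. P5 minus P6 of pregnant mice has the most genes, 6363, and the interaction the fewest, 23.

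The GFP reporter gave the second way of enrichment. GFPhi and GFPlo were 1 array each from virgin mice, so their differences are values of these arrays, with no replicate check. Basal genes were higher in GFPhi, led by Col17a1 (5.01), Cnn1 (4.93), Synm (4.80), Trp63 (4.49) and Krt23 (4.45). Lower were Gria1 (-4.72), Hsd11b1 (-4.70), Enpp2 (-4.67) and, among lipid and matrix genes, Lpl (-4.22) and the laminin chain Lama2 (-4.15). The basal list was higher in 16 of 17 members, with a median of 3.02 above all matched random lists (percentile 100). Stem-cell-associated genes (0.70; 12 of 14 higher), luminal progenitor (0.59; 10 of 13), general luminal (0.44; 13 of 16), milk (0.82; 15 of 17), basement membrane (0.68; 13 of 22) and cell cycle genes (0.32; 27 of 30) also stood at percentile 100. Endothelial markers (0.35; 11 of 15 higher) stood at 99.9 and Wnt genes (0.15; 18 of 32) at 98.9. The random lists did not match the correlation among members, so an extreme percentile is no test. All 19 fibroblast markers were lower (median -2.53, percentile 0), as were 11 of 15 mesenchymal genes (-0.90, percentile 0), 10 of 15 early response and heat shock genes (-0.93, percentile 0) and all 8 pericyte markers (-1.07, percentile 0.01).

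GFPhi minus GFPlo was set against the CD24 and CD29 gates over 23621 genes (23622 for P5 minus P6), which are not independent replicates. It correlated with P4 minus the mean of P5 and P6 in virgin mice at Pearson 0.575 and Spearman 0.334, with 58.9% of genes of the same sign. With P4 minus P6 the values were 0.740, 0.506 and 64.2%, with P4 minus P5 0.133, 0.025 and 49.8%, and with P5 minus P6, both depleted populations, 0.485, 0.341 and 60%. With the scanner's log ratio the first correlation was 0.448. GFPhi correlated at 0.873 with virgin P4 replicate 1, and GFPlo at 0.871 with virgin P6 replicate 1, arrays of the same scan.

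The genes of the sorting antibodies, which set the gates and are no findings between them, were read as a check of the labels. Cd24a, which encodes CD24, was lowest in P6, with P4 minus P6 at 2.53 and P5 minus P6 at 4.29 in virgin mice (adjusted p = 0.0034 and 0.000111) and 3.28 and 5.77 in pregnant mice. P5 exceeded P4 in both, by a P4 minus P5 difference of -1.76 (adjusted p = 0.02) and -2.49 (adjusted p = 0.00227, lost with median centring and without scan 3). Itgb1, which encodes CD29, differed between P4 and P5 by 1.19 in virgin mice (adjusted p = 0.195, or 0.00382 with the replicate number as a block in each condition, and past the threshold with slide or scan too) and 2.42 in pregnant mice (adjusted p = 0.00818, lost with median centring and without pregnant P4 replicate 1 or P5 replicate 2), although both carry the same CD29 label. Ptprc, which encodes the leukocyte antigen CD45, passed in no comparison, and Pecam1, which encodes the endothelial antigen CD31, was higher in P4 than in P5 by 1.14 in virgin mice (adjusted p = 0.0204) and 1.56 in pregnant mice (adjusted p = 0.00278). The virgin P4-P5 calls of Cd24a and Pecam1 were each lost without any 1 of these 4 arrays. Leukocyte markers lay higher in the enriched virgin populations (median 0.38; camera adjusted p = 0.00517, and adjusted p = 0.628 with an estimated correlation) and in virgin P4 over P5 (median 0.52; camera adjusted p = 0.0305, and adjusted p = 0.704 with an estimated correlation). Erythroid and nerve and glial markers passed camera in no comparison, with enriched-minus-depleted medians in virgin mice of 0.11 (camera adjusted p = 0.787) and 0.08 (camera adjusted p = 0.922), where the mean of the nerve list was -0.05. A list's median, mean and test differed in sign in 22 of the 252 pairs of list and comparison, and 0 of these passed camera. They include the milk list in the same comparison, with a median of 0.11 and a test pointing down, and the basal list in the pregnancy effect of P4, with a mean of -0.05 and a test pointing up. They also include the luminal progenitor list in that of P5, with a median of 0.46 and a mean of -0.14.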

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

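In this part the tests of adipocyte RNA and of the scan as a source of the Lep difference were chosen after the result was seen. The interaction test picked out 23 genes whose enriched-minus-depleted difference was not the same in virgin and pregnant mice. Among those named, the difference was larger in pregnant mice for Lep (3.78), Ppm1l (2.95), Amhr2 (2.47), Pdzd3 (2.36), Sh3rf2 (1.79), Lct (1.75), Cnmd (1.74), Arhgap18 (1.73), Pcbd1 (1.58) and Slc45a4 (1.55) and smaller for Lgr5 (-2.87), Speer5-ps1 (-2.19), Abcg5 (-2.09), Speer4d (-2.01), Foxj1 (-1.95) and Rimklb (-1.17). The same test shifted the medians of 8 lists: hormone-sensing luminal (0.71), cholesterol synthesis (0.078), cell cycle (-0.64), Notch (0.45), endothelial (0.81), pericyte (0.84), adipocyte (1.12) and early response and heat shock genes (1.61). Of these only the adipocyte list passed with an estimated correlation (adjusted p = 0.0477), and with slide as a block the hormone-sensing (adjusted p = 0.0562), endothelial (0.123) and pericyte (0.0511) lists no longer passed, nor with scan as a block the cholesterol list (adjusted p = 0.0776). Without scan 3 the cholesterol (adjusted p = 0.349) and pericyte (0.0909) lists no longer passed, nor the cholesterol list with the replicate number as a block in each condition (adjusted p = 0.0884). Within scan 2 the medians of these 8 lists were 1.23, -0.0021, -0.75, 0.42, 0.54, 0.63, 0.59 and 1.01. With the replicate number as a block in each condition 7 of the 16 genes no longer passed, Ppm1l (adjusted p = 0.123), Slc45a4 (0.119), Arhgap18 (0.0883), Lgr5 (0.0756), Speer5-ps1 (0.069), Sh3rf2 (0.0677) and Pcbd1 (0.0501).

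Lep, known as a hormone of fat cells, was weighed further, although its interaction did not pass with the scanner's log ratio. RNA from adipocytes might account for it in replicate 1 of pregnant P4, where the median over the 10 other adipocyte markers was 4.01. In replicate 2 that median was 1.10 and Lep 4.78, and the 3 arrays outside pregnant P4 with at least that median had Lep lower by 4.17 or more, which argues against adipocyte RNA as the whole source there. The 11 listed markers are on no other list. All were well above background in virgin P4, so the CD24 gate did not exclude their RNA. With scan as a block the pregnancy difference of Lep in P4 was 4.13 (SE 0.287), and within scan 2 it was 4.50, which argues against the scan, so higher Lep in P4 of pregnant mice stays open as a biological hypothesis, found and tested on the same arrays.

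The F test picked out 1877 genes whose pregnancy effect was not the same in P4, P5 and P6. For its 10 leading genes the largest minus the smallest effect was 5.76 for Abcg2, 6.18 for Stc2, 4.25 for Ido1, 4.24 for Kctd16, 4.27 for Egf, 3.82 for Prom1, 4.38 for Tmem159, 4.75 for Drd4, 3.73 for Cxcl15 and 6.21 for St6gal1. All 10 passed in each fit that left out 1 array, and with slide or scan as a block, but Kctd16 did not with backgrounds as given.

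A single array stood far from the others of its class in 5 of 72 tests of a named gene within a class of 4 or 5 arrays, where chance at 1 in 20 gives 3.6. The gap to the nearest array was 0.872 of the range for Speer4d in GFPlo, 0.913 for Tagln and 0.901 for Slc45a4 in replicate 1 of pregnant P6, and 0.841 for Arhgap18 and 0.875 for Foxj1 in replicate 2 of pregnant P5.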

How the results depend on the processing

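In this part the settings with backgrounds as given, without scan 3, with the replicate number as a block in each condition and, for lists, with slide or scan as a block were chosen after the data were seen; the other settings were planned. For changed values the cause was not tested, except where fewer arrays or genes entered the fit. Of 349 results for named genes, 0 moved under Aquantile scaling, which leaves ratios as they are and so tests nothing. The other settings ended the call of 6 without background correction, 53 with the scanner's log ratio, 52 of 348 with the series table, 65 with median centring, 6 without the filter, 7 of 288 with a filter in Cy3, 3 with all probes, 65 with slide and 9 with scan as a block and 15 with trend and robust. They ended 67 of 323 with only the arrays compared, 12 of 72 without the L2G85 arrays, 0 of 72 with 8 groups, 32 with backgrounds as given and 56 of 348 without scan 3. Leaving out 1 array ended 371 of 4331 calls, with a lone array assumed to vary like other groups. Aldh1a3, lower in P5 with pregnancy, turned to 0.022 with a filter in Cy3, where another probe stands for it.

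Enriched minus depleted of virgin mice (384 genes) gave 157 with median centring and 1589 with 8 groups, and of pregnant mice (590) 118 with slide as a block, 235 with only the arrays compared, 177 without scan 3 and 2966 with 8 groups. Their difference (23) gave 0 with the scanner's log ratio and 0 with the series table (unadjusted p under 0.05 in limma for 777 and 784), 13 with median centring, 2 with a filter in Cy3, 7 with slide as a block, 8 without scan 3 and 341 with 8 groups. Both unadjusted counts are under the 1 in 20 that chance alone would give. In virgin mice, P4 minus P5 (2685), P4 minus P6 (2440) and P5 minus P6 (3814) gave 1287, 1024 and 2143 with median centring, 5513, 4976 and 6580 with slide and 5731, 5167 and 6851 with scan as a block. In pregnant mice the same pairs (5337, 2857 and 6363) gave 2405, 1646 and 2774 with median centring, 9747, 5770 and 10470 with scan as a block, and 2869, 917 and 3549 with only the arrays compared. P4 minus P5 gave 3404 with backgrounds as given and P5 minus P6 10219 with slide as a block.

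The pregnancy effect in P4 (885) gave 446 with the scanner's log ratio, 461 with the series table, 190 with median centring, 1747 with scan as a block, 0 in limma with only the arrays compared (3854 at an unadjusted p under 0.05), 588 with backgrounds as given and 541 without scan 3. In P5 (5062) it gave 2421 with median centring, 8387 with scan as a block, 3336 with only the arrays compared and 3302 with backgrounds as given. In P6 (44) it gave 17 with the scanner's log ratio, 6 with median centring, 25 with a filter in Cy3, 9 with slide and 142 with scan as a block and 20 with trend and robust. It gave 0 in limma with only the arrays compared (1042 at an unadjusted p under 0.05), 8 with backgrounds as given and 8 without scan 3. The F test (1877) gave 427 with median centring, 5146 with slide and 6405 with scan as a block, 1055 with backgrounds as given and 1186 without scan 3. All other counts stayed within 1.5 times, apart from fits that left out 1 array and those with the replicate number as a block in each condition, given next.

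Leaving out each array gave 186 to 417 and 269 to 656 genes for enriched minus depleted in virgin and pregnant mice, 11 to 30 for their difference, 1293 to 2892, 1299 to 2592 and 2481 to 4022 for the virgin pairs in the order above. They gave 3210 to 5683, 2080 to 2773 and 4406 to 6340 for the pregnant pairs, 157 to 1001, 2373 to 5350 and 18 to 78 for the pregnancy effects, and 794 to 1885 for the F test. With the replicate number as a block these 13 counts were 434, 643, 26, 3439, 3162, 4640, 6778, 3592, 7798, 1275, 6528, 55 and 2789, all within 1.5 times. The block ended 8 calls of named genes and 3 of lists. As a block of its own in each condition, where the numbers pair the arrays, it gave 446, 727 and 20 for enriched minus depleted and their difference, 5733, 5166 and 6852 for the virgin pairs, 9747, 5770 and 10471 for the pregnant pairs and 6404 for the F test, while it cannot give a pregnancy effect. It ended 15 of 260 calls of named genes and 2 of 103 list calls, gave a call to Itgb1 in P4 minus P5 of virgin mice, and changed no other call of a named gene. It gave list calls to early response genes in enriched minus depleted of virgin mice, to cholesterol genes in P4 minus P6 of virgin mice, and to leukocyte markers in P4 minus P6 of both.

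Of 130 list calls, 30 passed with an estimated correlation. The scanner's log ratio ended 10, slide as a block 13, scan as a block 6 and leaving out scan 3 11. In the pregnancy effect of P6, slide as a block turned the luminal progenitor median to 0.029. The endothelial one turned to 0.28, or 0.033 without scan 3. The correlation of GFPhi minus GFPlo with the gates (0.575) was 0.448 with the scanner's log ratio, 0.566 without background correction and 0.581 with a filter in Cy3; with 1 array each it allows no paired fit. Signal over background limits dim genes, whose folds are bounds, and saturation limits milk genes in pregnant arrays.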

Other observations

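In this part the tests of stromal cells, of luminal and basal cells, of RNA from cells of the P5 type and of the scan were chosen after the result was seen. Gene groups not described above also moved between P4 and P5 of pregnant mice. Of 15 early response and heat shock genes 9 were higher in P4 (10 adjusted over the list alone; median 1.64; camera adjusted p = 1.74e-05, and adjusted p = 0.325 with an estimated correlation), and the median was 1.99 with slide as a block and 1.08 to 2.16 within batches. Of 8 pericyte markers 5 were higher in P4 (6 adjusted over the list alone; median 1.96; camera adjusted p = 0.00108, and adjusted p = 0.438 with an estimated correlation). Of 30 cell cycle genes 4 were lower in P4 (3 adjusted over the list alone; median -1.05; camera adjusted p = 0.000391, and adjusted p = 0.671 with an estimated correlation). Between P5 and P6 of pregnant mice, 5 of 13 luminal progenitor markers were higher and 1 lower in P5, also adjusted over the list alone (median 2.15; camera adjusted p = 0.0235, and adjusted p = 0.589 with an estimated correlation).

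The 384 genes of enriched minus depleted in virgin mice were set against other splits of the 8 virgin arrays into 3 and 5. The replicate numbers pair the wild-type ones (correlations of 0.31 to 0.679), so of all 56 splits those that take several arrays of 1 number, or not exactly 1 GFP array, are no fair measure of chance. Of the 18 that, like the real one, take 1 array of each replicate number and 1 GFP array, only the real split, 1 of 18, gave as many, and the highest other, both P6 arrays with GFPlo against the rest, gave 173. These are too few splits for a share under 0.05. Of the splits that follow a scan, 3 arrays of scan 1 (P6 and both GFP arrays) gave 73 and the 3 virgin arrays of scan 2 gave 3.

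Fibroblast markers were higher in P6 than in P4 and P5. Stromal cells in the CD24-low gate are a candidate explanation: 18 of the 19 markers were past the threshold and higher in virgin P6 than in both P4 and P5, with Col3a1 at a log2 ratio of 5.86, and that gate would not remove cells without CD24. None of the 19 is on another list, and all were well above background in virgin P4 and P5 too. Epithelial cells that keep their markers and also express fibroblast genes are argued against by the general luminal markers, with a median of -3.16 in P6 minus P5, and the basal markers, with -3.00 in P6 minus P4, and normalization by the scanner's log ratio, which gave a fibroblast median of 5.96. Epithelial cells that had lost these markers were not tested and stay open.

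Milk genes lay higher in P6 of pregnant than of virgin mice, with a median of 1.31 (adjusted p = 0.568 with an estimated correlation), while no milk gene passed over all genes. RNA from cells of the P5 type was weighed as a source of part of it. The measure was the share of P5 RNA that milk genes and the other genes at least 64-fold higher in pregnant P5 than in virgin P6 would need. In replicate 1 the 8 milk genes needed a median of 1.21% (-0.0442% to 34.7%; the 4 not saturated in P5 0.762%, up to 11.1% for Xdh), under the upper quartile of the 37 others (1.32%, median 0.695%). In replicate 2 the 12 milk genes needed 1.43% (-0.287% to 34.4%; the 7 not saturated 0.512%, up to 2.81% for Wfdc18), above that of the 34 others (0.947%, median 0.538%), while saturation in P5 raises a share and no single share met all of them. With scan as a block the milk median was 1.89, which argues against the scan, and a change within P6 cells in pregnancy stays open.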
